A study of Homo sapiens with 12 samples.

How the data were processed

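The 12 libraries came from human hepatic stellate cells bought as primary cells, which are the pericyte-like cells of the liver that turn into matrix-producing myofibroblasts during fibrosis. Per the labels' protocols, the cells were starved of serum overnight and then kept with or without 5 ng/ml of TGF-beta1, in the presence or absence of 5 uM of PF228, a compound known by its code name that inhibits focal adhesion kinase (the product of PTK2). Cells without the compound received its solvent DMSO and are called vehicle here. The 4 groups were vehicle, vehicle with TGF-beta1, PF228, and PF228 with TGF-beta1, with 3 libraries each. Libraries were made with a stranded poly(A) mRNA kit, per the series' design text. The labels do not say that the replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

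The authors deposited 1 table of FPKM values (fragments scaled by the length of the gene and the size of the library), with 1 value per gene symbol and library and no read counts. Per the submitters' processing notes, CASAVA 1.8.2, Trimmomatic 0.33, FastQC, Bowtie2 2.2.4.0, edgeR and the human build hg19 were used. These notes give neither the role nor the order of the tools, and the tool that made the FPKM values, its gene annotation and whether it used strand are not given in the sources used here. The table listed 26381 gene symbols. XIST, TSIX and genes of the Y chromosome (97 symbols) were left out of every step, which left 26284. Of these, 8660 (33.0%) were at 0 in all 12 libraries. They included TUBB, a tubulin gene in general use, 18 of 27 listed HLA genes and 133 of 158 listed genes of the MHC region, so an exact 0 can be a failed estimate and is described only as a gene listed at 0. The 11 symbols that reached 100 FPKM in a library but were above 0 in at most 2 libraries were all small RNAs. Total FPKM ranged from 407282 to 470033 between libraries.

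The depth of the libraries in reads is unknown, since the table holds no counts. Relative depth was read from the low values, which move in steps of what 1 fragment is worth. For each library, the most common ratio to vehicle replicate 1 was taken over genes above 0 and under 0.2 FPKM in both. Between 17.3% and 20.8% of these low genes lay within a log2 window of 0.01 at that ratio. With vehicle replicate 1 set to 1, relative depth was 1.36 and 1.1 in vehicle replicates 2 and 3, then 1.11, 0.92 and 0.7 in vehicle with TGF-beta1, 1.1, 1.01 and 1.11 in PF228, and 0.97, 0.89 and 0.8 in PF228 with TGF-beta1. Low values were therefore least precise in replicate 3 of vehicle with TGF-beta1. No interval that needs read counts is given.

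FPKM are not counts, so count models were not used. Values were analysed as log2(FPKM + 1), without further scaling between libraries, for the 11124 genes with at least 1 FPKM in at least 3 of the 12 libraries. The pseudocount of 1 makes the fold changes of low genes smaller than they are. All 12 libraries were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per group, an intensity trend and 8 residual degrees of freedom. The 5 tests per gene were TGF-beta1 in vehicle, TGF-beta1 in PF228, PF228 without TGF-beta1, PF228 with TGF-beta1, and the interaction, which is the TGF-beta1 response in PF228 minus that in vehicle. Tests were 2-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called higher or lower. A log2 change is given with its standard error (SE), and a group mean with the SD of 3 libraries. The share of the TGF-beta1 response kept in PF228 was the ratio of the log2 changes in PF228 and in vehicle, as the median over genes called in vehicle with at least a 2-fold change.

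The 31 gene lists were fixed before the data were examined: TGF-beta and SMAD target genes; contractile and cytoskeletal genes of myofibroblasts; fibrillar collagens and matrix proteins; collagen folding, crosslinking and processing enzymes; matrix proteases and their inhibitors. They also covered TGF-beta family ligands, receptors and SMADs, BMP and ID target genes, focal adhesion and integrin genes, YAP and TEAD target genes, SRF and MRTF target genes, G1/S and DNA replication genes, G2/M and mitosis genes, genes of quiescent stellate cells, inflammatory cytokines and NF-kappaB target genes, and interferon-stimulated genes. Further lists were cholesterol synthesis and SREBP target genes, unfolded protein response genes, ATF4 and amino acid supply genes, hypoxia and glycolysis genes, p53 target genes, immediate early and growth factor response genes, aryl hydrocarbon receptor target genes, NRF2 target genes, cytosolic ribosomal protein genes, replication-dependent histone genes and mitochondrially encoded mRNAs. Markers of other cells covered hepatocytes, endothelial cells, macrophages and leukocytes, cholangiocytes and epithelium, and portal fibroblasts and mesothelium. Lists share members (ACTA2 is a contractile and an SRF gene, CTGF a SMAD and a YAP gene), so their results are not independent. The 27 lists with at least 3 tested genes were tested with camera (limma), which asks whether a list's genes changed more in one direction than other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. Called members are given from the adjustment over all genes tested and as adjusted over the list alone.

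The genes named in the text followed a rule fixed before the data were examined. In each comparison it took the 6 genes with the largest positive and the 6 with the largest negative log2 change among called genes with a mean of at least 2 FPKM in a compared group and no overlap between the 3 and 3 libraries (for the interaction, called and at least 2 FPKM in any group). It also took up to 4 members per described list with the smallest adjusted p and at least 2 FPKM in a compared group, and, whatever their result, PTK2, PTK2B, TGFBR1, TGFBR2, ACTA2, TAGLN, COL1A1, COL1A2, COL3A1, FN1, SMAD7, CTGF, POSTN, TIMP1 and LOX. Some genes that the rule took are not reported here, and no gene replaced them. Pseudogenes, small RNAs and unnamed loci were left out of the largest changes. Any other gene is named with the reason. GC content and biotype came from GENCODE 29 on the build GRCh38, matched by symbol, and no coordinates are given, since the authors' build was hg19.

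The procedure was tested on simulated data made from the 12 libraries, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each of the 5 comparisons, run on 11124 genes. For TGF-beta1 in vehicle 83.6%, 88.1% and 97% of them were recovered with 9 false calls, and for TGF-beta1 in PF228 74.6%, 89.6% and 95.5% with 17. For PF228 without TGF-beta1 67.2%, 88.1% and 98.5% were recovered with 9 false calls, and for PF228 with TGF-beta1 70.1%, 91% and 98.5% with 12. For the interaction 46.3%, 82.1% and 92.4% were recovered with 14 false calls. A simulated share kept of 0.7 was returned as 0.693, and 0 of 135 list tests were called with no effect present. The residuals were drawn for each gene on its own, which removes the correlation between genes. The list result therefore does not test camera on correlated genes.

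Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a filter at 5 FPKM, upper-quartile scaling, quantile normalization, the replicate number as a block, no intensity trend, library weights, only the compared groups in the fit, each library left out in turn, a 2-fold minimum, and for the share a log2 minimum of 0.5 and genes chosen on other libraries. Added after seeing the data were the first component of the residuals within groups as a covariate, removal of each library's trend on GC content, and the same genes without that removal. Where the text gives the adjusted p of 1 alternative, the range beside it runs over every alternative of that result fitted with the same test. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.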

Results

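Expression was measured by poly(A) RNA sequencing in human hepatic stellate cells given vehicle, TGF-beta1, the focal adhesion kinase inhibitor PF228, or both, with 3 libraries per group. In a principal component analysis of the 11124 tested genes, the first component held 77.6% of the variance and separated libraries with TGF-beta1 from those without, and the second held 11.7% and separated PF228 from vehicle. Correlations (Pearson, across genes) were 0.989 to 0.997 within groups and 0.903 to 0.985 between groups, and no pair of libraries was a duplicate. The median SD of the log2 values was 0.072 in vehicle, 0.071 in PF228, 0.076 in PF228 with TGF-beta1 and 0.116 in vehicle with TGF-beta1, whose replicate 3 had the lowest relative depth (0.7, with vehicle replicate 1 set to 1). PTK2, which encodes the target of PF228, was expressed in all groups, at 19.9 ± 0.571 FPKM (SD, n = 3) in vehicle, 18.7 ± 0.629 in vehicle with TGF-beta1, 21.1 ± 0.246 in PF228 and 21.9 ± 0.97 in PF228 with TGF-beta1. The related kinase PTK2B was at 1.37 ± 0.194, 1.14 ± 0.231, 1.31 ± 0.0666 and 1.03 ± 0.106 FPKM in the same order. Of the other liver cells, no hepatocyte marker passed the filter, and the highest value of any in a library was 0.941 FPKM (CPS1). Albumin (ALB) reached 0.054 FPKM. Apart from CD68 and CD74, leukocyte markers stayed at or below 0.484 FPKM, and apart from KDR and TEK, named because they were the 2 endothelial markers tested, endothelial markers stayed at or below 0.426 FPKM in every library.

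The first comparison asked what TGF-beta1 does to stellate cells in the absence of the inhibitor. TGF-beta1 raised the smooth muscle actins most. ACTA2, the usual marker of activated stellate cells, went from 82.6 ± 3.18 to 4326 ± 361 FPKM (SD, n = 3; log2 change 5.69 ± 0.056, adjusted p = 1.61e-16), and ACTG2 from 10.3 ± 0.629 to 686 ± 64.4 (5.92 ± 0.093). IGFBP3, an insulin-like growth factor binding protein, went from 23.5 ± 1.09 to 1083 ± 0.417 FPKM (5.47 ± 0.041), and the matricellular gene CTGF from 91.7 ± 2.17 to 3543 ± 7.26 (5.26 ± 0.033). The calponin gene CNN1 (4.96 ± 0.093) and PMEPA1, a feedback inhibitor of TGF-beta signalling (4.90 ± 0.065), completed the 6 largest increases, with adjusted p at most 6.64e-14. The largest decrease was in ADH1B, an alcohol dehydrogenase, from 115 ± 4.84 to 0.538 ± 0.0749 FPKM (-6.23 ± 0.075), followed by CLDN11, which encodes a tight junction claudin (-4.97 ± 0.037). NOV, a relative of CTGF (-4.24 ± 0.085), the hyaluronan-degrading CEMIP (-4.10 ± 0.064) and FAXDC2 (-3.85 ± 0.058) also fell, with adjusted p at most 1.36e-13.

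In all, 7805 genes were called, 3991 higher and 3814 lower, of which 812 and 702 changed at least 2-fold. The share of calls that were higher was 51.1% as deposited, 48.8% under quantile normalization and 42.3% with upper-quartile scaling. Of the 31 tested TGF-beta and SMAD target genes, 27 were higher and 3 lower (27 and 3 adjusted over the list alone), with a median log2 change of 2.17 (camera, adjusted p = 2.5e-11). ADAM12 (3.88 ± 0.050) and the inhibitory SMAD7 (1.94 ± 0.079) rose, with adjusted p at most 1.28e-10. Of the receptors, TGFBR1 rose (1.80 ± 0.056, adjusted p = 9.01e-12) and TGFBR2 fell (-1.08 ± 0.041, adjusted p = 5.98e-11). PTK2 did not pass (-0.08 ± 0.049, adjusted p = 0.157), except for a lower call with library weights (adjusted p = 0.0049), the first residual component as a covariate (0.042), upper-quartile scaling (0.00407) and quantile normalization (0.00538, range 0.00407 to 0.4). The 35 tested TGF-beta family ligands, receptors and SMADs went both ways, and 17 were higher and 10 lower (17 and 10 adjusted over the list alone; camera, adjusted p = 0.201). Among them DACT1 (3.01 ± 0.066), the activin subunit INHBA (3.24 ± 0.089) and LRRC32, which holds latent TGF-beta at the cell surface (2.74 ± 0.065), rose and the co-receptor TGFBR3 fell (-2.53 ± 0.050). Of 21 contractile and cytoskeletal genes of myofibroblasts, 20 were higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 2.24 (adjusted p = 2.12e-13). They included tropomyosin TPM1 (3.98 ± 0.038), the cardiac actin ACTC1 (4.85 ± 0.060) and TAGLN, or SM22 (3.82 ± 0.062). The overlapping SRF and MRTF target genes had a median of 1.94, and 26 were higher and 2 lower (26 and 2 adjusted over the list alone) of 28 (adjusted p = 2.12e-13). Of 58 focal adhesion and integrin genes, 41 were higher and 7 lower (42 and 8 adjusted over the list alone), with ITGA1 (3.50 ± 0.065), ACTN1 (2.82 ± 0.050) and VASP (2.13 ± 0.055) among the higher (adjusted p = 5.58e-07). Of 22 YAP and TEAD target genes, 15 were higher and 6 lower (15 and 6 adjusted over the list alone; adjusted p = 0.00859), and CYR61 rose by 2.74 ± 0.036.

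**Figure D1:**
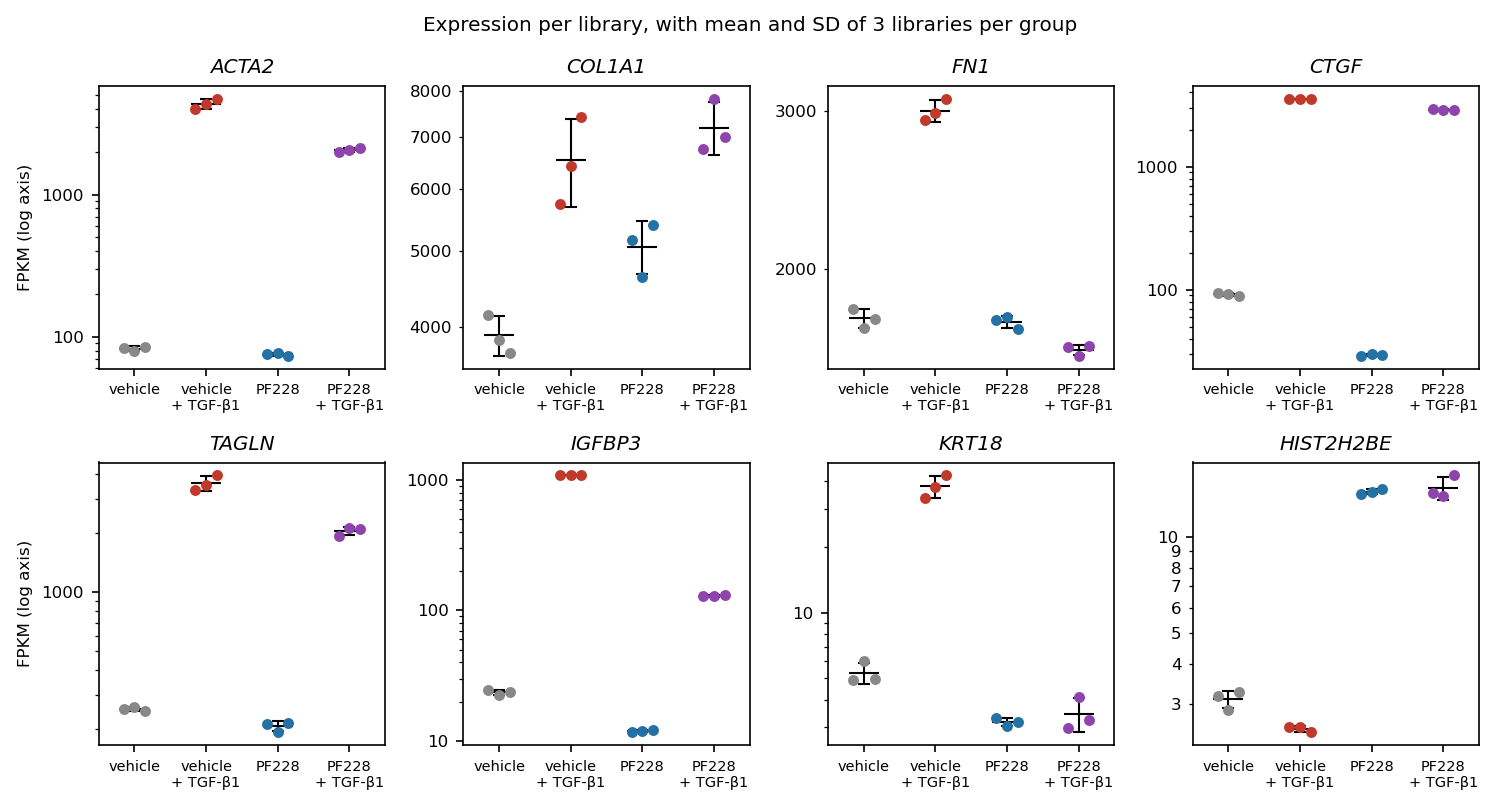
FPKM of 8 genes on log axes, with 1 point per library and the mean and SD of 3 libraries per group (vehicle, vehicle with TGF-beta1, PF228, PF228 with TGF-beta1). ACTA2 averaged 82.6, 4326, 75.6 and 2065 FPKM in that order and FN1 1764, 3001, 1748 and 1628.

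Matrix genes moved less uniformly. Of 45 fibrillar collagens and matrix proteins, 31 were higher and 13 lower (31 and 13 adjusted over the list alone), with a median of 0.51 (camera, adjusted p = 0.000947; adjusted p = 0.163 with an estimated correlation). Tenascin TNC (2.68 ± 0.051), the basement membrane collagen COL4A1 (2.43 ± 0.049), THBS1 (1.94 ± 0.035) and SPARC (1.73 ± 0.030) rose most firmly. The fibrillar collagens rose less from high levels, COL1A1 from 3907 ± 226 to 6534 ± 838 FPKM (0.73 ± 0.088), and COL1A2 from 5034 ± 185 to 6733 ± 388 (0.42 ± 0.045). COL3A1 went from 2192 ± 53.9 to 2751 ± 111 FPKM (0.33 ± 0.038), a call that ended under quantile normalization (adjusted p = 0.393, range 1.81e-09 to 0.393). Fibronectin FN1 went from 1764 ± 43.7 to 3001 ± 84.6 FPKM (0.77 ± 0.036, adjusted p = 4.58e-10). Periostin POSTN did not pass the test (-0.12 ± 0.069, adjusted p = 0.155), although it was called lower without replicate 1 of vehicle with TGF-beta1, among other alternatives (adjusted p = 0.0191, range 0.000188 to 0.635). Of 23 collagen folding, crosslinking and processing enzymes, 18 were higher and 3 lower (18 and 3 adjusted over the list alone; adjusted p = 0.000266; adjusted p = 0.173 with an estimated correlation). Among them were the lysyl hydroxylase PLOD2 (2.73 ± 0.074), the prolyl hydroxylase P4HA3 (2.67 ± 0.095) and lysyl oxidase LOX (1.25 ± 0.051). Of 25 matrix proteases and their inhibitors, 10 were higher and 11 lower (11 and 11 adjusted over the list alone), and the list did not pass (adjusted p = 0.647). The inhibitor SERPINE2 rose (1.93 ± 0.039) and the aggrecanase ADAMTS5 (-2.95 ± 0.065) and TIMP1 (-0.28 ± 0.063) fell.

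Of 35 ATF4 and amino acid supply genes, 33 were higher and 0 lower (33 and 0 adjusted over the list alone), with a median of 1.25 (camera, adjusted p = 1.14e-12). Examples were the transporter SLC1A4 (2.88 ± 0.059), asparagine synthetase ASNS (2.42 ± 0.054) and the serine synthesis enzyme PSAT1 (2.22 ± 0.044). Of 28 unfolded protein response genes, 24 were higher and 3 lower (24 and 3 adjusted over the list alone; adjusted p = 1.55e-06), including XBP1 (2.05 ± 0.047) and the chaperone HSPA5 (1.83 ± 0.043). Of 32 cholesterol synthesis and SREBP target genes, 26 were higher and 2 lower (26 and 2 adjusted over the list alone; adjusted p = 9.68e-06), including SQLE (1.48 ± 0.072), the desaturase SCD (1.25 ± 0.035) and FDPS (0.74 ± 0.043). Of 33 hypoxia and glycolysis genes, 21 were higher and 9 lower (21 and 9 adjusted over the list alone), with PFKP (2.38 ± 0.088) and the glucose transporter SLC2A1 (1.65 ± 0.067) higher and CA12 (-1.68 ± 0.066) lower. That list's call (adjusted p = 0.037) ended without replicate 3 of vehicle with TGF-beta1 (adjusted p = 0.0508), with a filter at 5 FPKM (0.0772), with the GC trend removed (0.0505) and under quantile normalization (0.104, range 0.0143 to 0.104), and it had adjusted p = 0.173 with an estimated correlation. The inhibitors of differentiation ID1 (2.24 ± 0.12), ID3 (2.44 ± 0.13) and ID4 (2.20 ± 0.089) rose. Of the 11 tested BMP and ID target genes, 5 were higher and 4 lower (5 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.627).

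Genes of quiescent stellate cells, interferon-stimulated genes, p53 target genes and cytosolic ribosomal protein genes were ranked downwards. Of 19 tested genes of quiescent stellate cells, 7 were higher and 12 lower (7 and 12 adjusted over the list alone), with a median of -0.95 (camera, adjusted p = 0.0189; adjusted p = 0.0594 with an estimated correlation). Hepatocyte growth factor HGF (-3.04 ± 0.074), the PDGF receptor PDGFRA (-2.27 ± 0.038) and IGFBP5 (-2.19 ± 0.036) were among those that fell, with adjusted p at most 7.71e-13. The list held 33 genes, and those not tested were below the filter. Examples, named for that reason, were LRAT, listed at 0, and GFAP, at most 0.089 FPKM in any library. Of 26 interferon-stimulated genes, 4 were higher and 17 lower (4 and 17 adjusted over the list alone), with IFIT3 (-2.12 ± 0.10) and STAT2 (-0.92 ± 0.047) lower and XAF1 (1.71 ± 0.10) higher (adjusted p = 0.011). Of 29 p53 target genes, 8 were higher and 18 lower (8 and 18 adjusted over the list alone), with CCNG1 (-2.02 ± 0.079) and DDB2 (-1.63 ± 0.072) lower. The test gave adjusted p = 0.0386 (adjusted p = 0.0774 with an estimated correlation, and 0.0564 with upper-quartile scaling, range 0.0168 to 0.0564). Of 70 cytosolic ribosomal protein genes, 0 were higher and 40 lower (0 and 39 adjusted over the list alone), with a median of -0.17. RPL15 was at -0.54 ± 0.035 and RPL23 at -0.34 ± 0.035. The list was past the test (adjusted p = 0.000171; adjusted p = 0.319 with an estimated correlation). Of 18 inflammatory cytokines and NF-kappaB target genes, 4 were higher and 9 lower (4 and 9 adjusted over the list alone; adjusted p = 0.108, and 0.0436 with a filter at 5 FPKM, range 0.0436 to 0.263), with the chemokine CXCL12 lower (-2.85 ± 0.046) and TNFAIP6 higher (2.93 ± 0.062). Of 29 immediate early and growth factor response genes, 8 were higher and 16 lower (8 and 16 adjusted over the list alone; adjusted p = 0.105), with PHLDA1 lower (-2.63 ± 0.057) and EGR2 (2.92 ± 0.067) and HBEGF (2.97 ± 0.066) higher.

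The remaining lists did not pass the test with TGF-beta1 in vehicle. Of 22 G1/S and DNA replication genes, 5 were higher and 10 lower (5 and 10 adjusted over the list alone), with TYMS at -1.40 ± 0.065 (camera, adjusted p = 0.0948, and 0.0168 with a filter at 5 FPKM, range 0.0168 to 0.274). Of 14 G2/M and mitosis genes, 2 were higher and 7 lower (2 and 6 adjusted over the list alone), with CCNA2 higher (1.35 ± 0.098) and CCNB2 lower (-0.90 ± 0.11; adjusted p = 0.424, and 0.0492 without the filter, range 0.0492 to 0.711). Of 25 NRF2 target genes, 11 were higher and 9 lower (11 and 9 adjusted over the list alone), with SRXN1 at 0.94 ± 0.046 and TKT at -1.55 ± 0.085 (adjusted p = 0.892). Of 5 aryl hydrocarbon receptor target genes, 2 were higher and 2 lower (2 and 2 adjusted over the list alone), with the amino acid transporter SLC7A5 higher (3.26 ± 0.094) and AHRR lower (-1.37 ± 0.076; adjusted p = 0.943). The median of that list was 0.01 and its mean 0.32, while camera ranked it downwards. Of 10 replication-dependent histone genes, 0 were higher and 6 lower (0 and 6 adjusted over the list alone), with HIST1H2BD at -0.98 ± 0.12 (adjusted p = 0.0828, and 0.0489 with library weights, range 0.0489 to 0.275). Epithelial keratins were among the markers that rose, KRT7 from 0.579 ± 0.343 to 16.1 ± 2.07 FPKM (3.45 ± 0.15) and KRT18, which has many processed pseudogenes and is therefore uncertain, from 5.3 ± 0.61 to 38 ± 4.54 (2.63 ± 0.11). Of 6 cholangiocyte and epithelial markers, 4 were higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0948). Of 6 portal fibroblast and mesothelial markers, 4 were higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.071), with elastin ELN at 4.38 ± 0.11. The latter list passed without replicate 1 of vehicle (0.0497) or of vehicle with TGF-beta1 (0.0395, range 0.0395 to 0.451). Of the 2 tested macrophage and leukocyte markers, 0 were higher and 2 lower. CD68 fell (-0.57 ± 0.070), and the call of CD74 (-0.38 ± 0.13, adjusted p = 0.0188) ended without replicate 1 or 3 of vehicle (0.0832 and 0.0542) or replicate 2 of vehicle with TGF-beta1 (0.0905) and under quantile normalization (0.108, range 2.97e-05 to 0.108). Of the 2 tested endothelial markers, 0 were higher and 2 lower. Camera calls that held with an estimated correlation were those of the SMAD, contractile, focal adhesion, YAP, SRF, interferon, cholesterol, unfolded protein response and ATF4 lists, with adjusted p between 0.000629 and 0.041. Mitochondrially encoded mRNAs were not analysed here.

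The second comparison asked for the response to TGF-beta1 when PF228 was present. CTGF rose from 29.7 ± 0.504 to 2906 ± 14.4 FPKM (SD, n = 3; log2 change 6.57 ± 0.033, adjusted p = 1.8e-19). ACTG2 rose from 4.28 ± 0.741 to 216 ± 9.67 (5.37 ± 0.093). PMEPA1 (5.34 ± 0.065), ACTC1 (4.96 ± 0.060) and CNN1 (4.87 ± 0.093) were also among the 6 largest increases, and ACTA2 rose from 75.6 ± 1.8 to 2065 ± 68 FPKM (4.75 ± 0.056). ADH1B (-6.63 ± 0.075), CLDN11 (-4.98 ± 0.037), NOV (-3.89 ± 0.085), the immune checkpoint gene C10orf54 (-3.65 ± 0.091), SECTM1 (-3.62 ± 0.073) and FAXDC2 (-3.34 ± 0.058) fell most, with adjusted p at most 1.2e-12.

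In PF228, 7357 genes were called with TGF-beta1, 3794 higher and 3563 lower, of which 650 and 484 changed at least 2-fold. The share of calls that were higher was 51.6% as deposited, 47.7% under quantile normalization and 41.0% with upper-quartile scaling. Of the 7357 genes, 3246 were higher and 3030 lower in vehicle as well, where independent calls would give 1361 and 1222. The vehicle and PF228 responses share no library, and across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.917 and Spearman's rho = 0.900. Of the TGF-beta and SMAD target genes, 28 were higher and 3 lower (28 and 3 adjusted over the list alone) of 31, with a median of 2.34 (camera, adjusted p = 1.54e-13), and SMAD7 rose by 2.34 ± 0.079. Of the contractile genes, 20 were higher and 1 lower (20 and 1 adjusted over the list alone) of 21 (adjusted p = 1.29e-12), with TPM1 at 4.38 ± 0.038 and TAGLN at 3.31 ± 0.062. The SRF (median 2.07, adjusted p = 2.07e-14), focal adhesion (0.48, 6.21e-07), ATF4 (1.28, 5.94e-13) and unfolded protein response (0.50, 9.51e-06) lists rose as well. MICAL2 (4.27 ± 0.061), NEDD9 (2.62 ± 0.069), MTHFD2 (2.31 ± 0.049) and XBP1 (2.01 ± 0.047) were members of these lists. Interferon-stimulated genes fell, and 2 were higher and 18 lower (2 and 18 adjusted over the list alone) of 26, with IFIT3 at -2.39 ± 0.10 (adjusted p = 0.000447). The inflammatory list fell, with CXCL12 at -2.58 ± 0.046 (adjusted p = 0.0133; adjusted p = 0.054 with an estimated correlation). Of the collagen enzymes, 14 were higher and 3 lower (14 and 3 adjusted over the list alone) of 23 (adjusted p = 0.00853; adjusted p = 0.321 with an estimated correlation), led by PLOD2 (2.99 ± 0.074). Of 70 cytosolic ribosomal protein genes, 0 were higher and 68 lower (0 and 69 adjusted over the list alone), with a median of -0.37 and RPL23 at -0.47 ± 0.035 (adjusted p = 1.97e-12; adjusted p = 0.124 with an estimated correlation).

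Matrix genes as a list did not pass with TGF-beta1 in PF228. Of 45 fibrillar collagens and matrix proteins, 21 were higher and 18 lower (21 and 18 adjusted over the list alone), with a median of 0.08 (camera, adjusted p = 0.554). COL1A1 (0.50 ± 0.088, adjusted p = 0.000226), COL1A2 (0.25 ± 0.045, adjusted p = 0.000288) and VCAN (2.00 ± 0.051) rose. COL3A1 did not pass (-0.05 ± 0.038, adjusted p = 0.273), although it was called lower with the first residual component as a covariate (adjusted p = 0.0436) and with upper-quartile scaling (0.00222, range 0.00222 to 0.513). FN1 was at 1748 ± 28.7 FPKM without and 1628 ± 21.1 with TGF-beta1 (-0.10 ± 0.036, adjusted p = 0.0219), a call that ended without replicate 1 or 2 of PF228 or replicate 2 of PF228 with TGF-beta1 (adjusted p = 0.0654 to 0.0718), without the filter (0.0596) and without the intensity trend (0.0708, range 0.000138 to 0.0718). POSTN was at 0.02 ± 0.069 (adjusted p = 0.839) and LOX rose by 1.08 ± 0.051. The genes of quiescent stellate cells, with PDGFRA at -2.22 ± 0.038, were at the edge of the test (adjusted p = 0.0496; adjusted p = 0.0962 with an estimated correlation). That call ended under most alternatives, among them the absence of replicate 1 or 2 of vehicle (0.0538 and 0.054), of replicate 1 or 3 of vehicle with TGF-beta1 (0.0539 and 0.0565) or of replicate 3 of PF228 with TGF-beta1 (0.0517, range 0.0108 to 0.1). Cholesterol synthesis and SREBP target genes, with SCD at 0.89 ± 0.035, did not pass (adjusted p = 0.0598), except without replicate 3 of PF228 (0.0427), with the first residual component as a covariate (0.048) and without the filter (0.0105, range 0.0105 to 0.158). Nor did YAP and TEAD target genes, with CYR61 at 3.73 ± 0.036 (adjusted p = 0.0941, and 0.0497 without the filter, range 0.0497 to 0.251). The median, mean and camera direction differed in sign for the TGF-beta family (-0.05, 0.33, up), G2/M (-0.04, 0.01, down), immediate early (-0.06, 0.12, down), aryl hydrocarbon receptor (-0.11, 0.34, down) and NRF2 lists (-0.04, 0.02, down), none of which passed. The SMAD, contractile, SRF, focal adhesion, ATF4, unfolded protein response and interferon calls held with an estimated correlation, with adjusted p at most 0.034.

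The third comparison asked what PF228 does to stellate cells without TGF-beta1. Changes were smaller than with TGF-beta1. MMP10, a stromelysin, fell from 7.89 ± 0.525 to 0.547 ± 0.105 FPKM (SD, n = 3; log2 change -2.52 ± 0.11, adjusted p = 6.02e-09), and the G protein regulator RGS4 from 15.6 ± 1.02 to 3.1 ± 0.0964 (-2.01 ± 0.073). CEMIP (-2.00 ± 0.064), the immediate early factor EGR3 (-1.85 ± 0.074) and the glutamate receptor GRIA1 (-1.79 ± 0.084) were also among the 6 largest decreases, with adjusted p at most 1.09e-08. The largest increases were in replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, and in TTC14, from 5.12 ± 0.183 to 22.9 ± 0.598 FPKM (1.96 ± 0.071). HIST2H2BE went from 3.09 ± 0.197 to 13.8 ± 0.234 FPKM (1.86 ± 0.065), and HIST1H2BC (2.15 ± 0.24), HIST1H2BG (2.06 ± 0.19) and HIST1H2AI (1.53 ± 0.15) rose as well. Histone genes are near-identical copies, so single values are uncertain. The readthrough gene RPS10-NUDT3 (1.60 ± 0.33) shares its exons with RPS10, and its call ended with a pseudocount of 0.01 (adjusted p = 0.071, range 1.23e-05 to 0.071).

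In all, 3883 genes were called with PF228 alone, 1580 higher and 2303 lower, but only 25 and 90 changed at least 2-fold. The share of calls that were higher was 40.7% as deposited and 51.4% under quantile normalization. Of 10 tested replication-dependent histone genes, 10 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 1.47 (camera, adjusted p = 1.58e-11), among them HIST1H1C (1.51 ± 0.099) and HIST1H2BK (1.05 ± 0.047). Of 32 cholesterol synthesis and SREBP target genes, 19 were higher and 3 lower (20 and 3 adjusted over the list alone), with a median of 0.25 (adjusted p = 3.5e-08), including SCD (0.93 ± 0.035), FADS1 (0.80 ± 0.040) and FADS2 (0.84 ± 0.072). Of 25 NRF2 target genes, 16 were higher and 2 lower (17 and 2 adjusted over the list alone), including PRDX1 (0.64 ± 0.042) and NQO1 (0.63 ± 0.050) among the higher and AKR1C3 (-0.82 ± 0.058) among the lower (adjusted p = 1.2e-07). Of 5 aryl hydrocarbon receptor target genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone), with the cytochrome CYP1B1 at 1.27 ± 0.070 (adjusted p = 0.013; adjusted p = 0.0558 with an estimated correlation, and 0.086 without the filter, range 0.00888 to 0.086). The list's CYP1A1, named because it was not tested, reached at most 0.056 FPKM in any library. The 70 cytosolic ribosomal protein genes were ranked slightly upwards (median 0.06, adjusted p = 0.0158; adjusted p = 0.495 with an estimated correlation), a direction that turned under quantile normalization (adjusted p = 0.987, range 0.00486 to 0.987). Of these genes, 8 were higher and 3 lower (1 and 1 adjusted over the list alone), with RPL36 at 0.21 ± 0.056 and RPS7 at -0.27 ± 0.044. The RPL36 call ended without replicate 3 of PF228 (adjusted p = 0.0618) and with the GC trend removed (0.0962, range 0.000257 to 0.0962).

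Among the lists that fell with PF228 alone, the contractile genes had a median of -0.30, and 1 was higher and 17 lower (1 and 18 adjusted over the list alone) of 21 (camera, adjusted p = 1.2e-07). ACTG2 (-1.11 ± 0.093), TPM1 (-1.06 ± 0.038) and TAGLN (-0.29 ± 0.062) fell, and ACTA2 did not pass (-0.12 ± 0.056, adjusted p = 0.0997). ACTA2 was called lower when replicate 1 or 3 of vehicle with TGF-beta1, which share in the estimate of the spread, was left out, and under other alternatives (adjusted p = 0.0458 and 0.032, range 0.00209 to 0.263). Of the TGF-beta and SMAD target genes, 2 were higher and 14 lower (2 and 15 adjusted over the list alone) of 31 (adjusted p = 0.000565). CTGF went from 91.7 ± 2.17 to 29.7 ± 0.504 FPKM (-1.59 ± 0.033) and the NADPH oxidase NOX4 was at -1.57 ± 0.086. YAP and TEAD target genes fell (adjusted p = 0.0017), with CYR61 at -0.88 ± 0.036 and IGFBP3 at -0.92 ± 0.041. SRF and MRTF target genes, with MICAL2 at -1.15 ± 0.061, had adjusted p = 0.015, and adjusted p = 0.393 with an estimated correlation. Of 26 interferon-stimulated genes, 0 were higher and 17 lower (0 and 19 adjusted over the list alone), with IFITM1 (-1.28 ± 0.12) and IFI35 (-0.95 ± 0.081) lower (adjusted p = 1.7e-05). Inflammatory cytokines and NF-kappaB target genes fell (adjusted p = 0.0032, and 0.352 with a filter at 5 FPKM, range 0.00144 to 0.352), with the chemokine CCL2 at -1.27 ± 0.18. ATF4 and amino acid supply genes fell, and 3 were higher and 23 lower (3 and 23 adjusted over the list alone) of 35, with MTHFD2 at -0.72 ± 0.049 and STC2 at -0.77 ± 0.056 (adjusted p = 1.7e-05). Of 22 G1/S and DNA replication genes, 1 was higher and 9 lower (1 and 10 adjusted over the list alone), with TYMS at -0.42 ± 0.065 and MCM6 at -0.45 ± 0.072. The test gave adjusted p = 0.0309 (adjusted p = 0.0719 with an estimated correlation, 0.0752 under quantile normalization and 0.239 with a filter at 5 FPKM, range 0.0164 to 0.239). Of 14 G2/M and mitosis genes, 0 were higher and 9 lower (0 and 9 adjusted over the list alone; adjusted p = 0.0224; adjusted p = 0.102 with an estimated correlation, 0.0523 with the first residual component as a covariate, 0.0908 with the GC trend removed and 0.882 with a filter at 5 FPKM, range 0.015 to 0.882).

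The chief fibrillar collagens were higher with PF228 alone. COL1A1 rose from 3907 ± 226 to 5072 ± 389 FPKM (0.38 ± 0.088, adjusted p = 0.00555) and COL3A1 from 2192 ± 53.9 to 2816 ± 20.9 (0.36 ± 0.038). COL1A2 went from 5034 ± 185 to 5758 ± 97.4 (0.19 ± 0.045, whose call ended under quantile normalization with adjusted p = 1, range 4.02e-05 to 1). POSTN fell from 491 ± 24.7 to 240.2 ± 8.49 FPKM (-1.03 ± 0.069) and LOX from 242 ± 10.2 to 142 ± 4.49 (-0.76 ± 0.051), and COL6A3 fell as well (-0.72 ± 0.038). FN1 was at -0.01 ± 0.036 (adjusted p = 0.81) and TIMP1 at 0.03 ± 0.063 (adjusted p = 0.773). The list of fibrillar collagens and matrix proteins, of which 8 were higher and 17 lower (9 and 17 adjusted over the list alone) of 45, did not pass (camera, adjusted p = 0.0909, 0.0205 with the GC trend removed and 0.00229 under quantile normalization, range 0.00229 to 0.185). The crosslinking enzyme TGM2 (-1.57 ± 0.071) and the collagenase MMP1 (-1.50 ± 0.058) fell, in lists that did not pass either (adjusted p = 0.291 and 0.333). The integrin ITGA8 fell (-1.48 ± 0.056) and the small GTPases RHOB (0.96 ± 0.054) and RHOA (0.62 ± 0.037) rose. Of 58 focal adhesion and integrin genes, 13 were higher and 16 lower (15 and 17 adjusted over the list alone; adjusted p = 0.765). PTK2 did not pass (0.09 ± 0.049, adjusted p = 0.197), except with the GC trend removed (adjusted p = 0.0071, range 0.0071 to 0.37), nor did TGFBR1 (0.00 ± 0.056, adjusted p = 0.961), and TGFBR2 rose by 0.16 ± 0.041. The median, mean and camera direction differed in sign for the collagen enzymes (0.09, -0.04, up), the focal adhesion list (-0.04, -0.01, up) and the hypoxia list (-0.003, -0.009, up). The histone, cholesterol, NRF2, contractile, SMAD, YAP, interferon, inflammatory and ATF4 calls held with an estimated correlation, with adjusted p at most 0.0229.

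The fourth comparison asked what PF228 does in the presence of TGF-beta1. IGFBP3 fell from 1083 ± 0.417 to 129 ± 1.8 FPKM (SD, n = 3; log2 change -3.06 ± 0.041, adjusted p = 3.99e-14). KRT18 fell from 38 ± 4.54 to 3.44 ± 0.603 (-3.14 ± 0.11) and COMP, a cartilage matrix protein, from 9.66 ± 2.01 to 0.939 ± 0.141 (-2.45 ± 0.12). RAMP1 (-2.46 ± 0.14), MMP10 (-2.44 ± 0.11) and CCL2 (-2.24 ± 0.18) were the others of the 6 largest decreases. ACTA2 fell from 4326 ± 361 to 2065 ± 68 FPKM (-1.06 ± 0.056, adjusted p = 2.2e-08), which left it far above its level without TGF-beta1. Among the 6 largest increases were TTC14 (2.36 ± 0.071) and the histone genes HIST1H2BC (2.33 ± 0.24), HIST2H2BE (2.12 ± 0.065), HIST1H2BD (1.85 ± 0.12) and HIST1H2AE (1.75 ± 0.14).

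Here 3995 genes were called, 1756 higher and 2239 lower, of which 33 and 129 changed at least 2-fold. Calls that were higher made up 44.0% as deposited, 49.6% with upper-quartile scaling and 52.6% under quantile normalization. With and without TGF-beta1, 741 genes were higher and 1189 lower with PF228, where independent calls would give 249 and 464, and 174 were called in opposite directions. The PF228 effects in the presence and absence of TGF-beta1 share no library, and they correlated across genes with Pearson's r = 0.547 and Spearman's rho = 0.548. Of 21 contractile genes, 0 were higher and 18 lower (0 and 18 adjusted over the list alone), with a median of -0.66 (camera, adjusted p = 9.38e-12). Those lower included desmin DES (-1.96 ± 0.095), ACTG2 (-1.66 ± 0.093), the kinase MYLK (-1.18 ± 0.062) and TAGLN (-0.80 ± 0.062). Of 45 fibrillar collagens and matrix proteins, 3 were higher and 31 lower (3 and 32 adjusted over the list alone), with a median of -0.28 (adjusted p = 9.38e-12). Those lower included TNC (-1.61 ± 0.051), COL6A3 (-1.23 ± 0.038), FN1 (-0.88 ± 0.036, from 3001 ± 84.6 to 1628 ± 21.1 FPKM) and POSTN (-0.90 ± 0.069). The chief fibrillar collagens did not pass, with COL1A1 at 0.14 ± 0.088 (adjusted p = 0.226), COL1A2 at 0.03 ± 0.045 (0.68) and COL3A1 at -0.01 ± 0.038 (0.793). Under quantile normalization COL1A2 was lower (-0.15) and COL3A1 higher (0.21), and COL1A1 was called higher without replicate 3 of vehicle with TGF-beta1, among other alternatives (adjusted p = 0.0311, range 0.00112 to 0.646). LOX (-0.93 ± 0.051) and LOXL4 (-1.20 ± 0.081) fell, and with them the list of collagen folding, crosslinking and processing enzymes (adjusted p = 0.028; adjusted p = 0.348 with an estimated correlation). Its call ended without replicate 3 of vehicle with TGF-beta1 (adjusted p = 0.174) or replicate 1 of PF228 with TGF-beta1 (0.0543), with library weights (0.0636) and under quantile normalization (0.133, range 0.0046 to 0.174). The protease ADAMTS1 (-1.65 ± 0.038), MMP1 (-2.07 ± 0.058) and TIMP3 (-0.88 ± 0.035) fell, although the matrix proteases and their inhibitors as a list did not pass (adjusted p = 0.0758). That list passed without replicate 1 or 2 of vehicle with TGF-beta1 (0.0477 and 0.0432) or replicate 2 of PF228 with TGF-beta1 (0.0424), with a filter at 5 FPKM (0.0228) and without a filter (0.0205, range 0.0205 to 0.302). PTK2 itself rose slightly (0.21 ± 0.049, adjusted p = 0.0042). CTGF was at -0.29 ± 0.033 (adjusted p = 0.272 under quantile normalization, range 9.62e-08 to 0.272). Of all 31 SMAD targets, 7 were higher and 12 lower (9 and 13 adjusted over the list alone), with TSC22D1 at 0.48 ± 0.048 (adjusted p = 0.315).

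YAP and TEAD target genes fell with PF228 in the presence of TGF-beta1, and 3 were higher and 12 lower (4 and 14 adjusted over the list alone) of 22 (camera, adjusted p = 0.000276), with TGFB2 at -1.29 ± 0.073 and CCDC80 at -0.83 ± 0.035. SRF and MRTF target genes, with MYL9 at -0.94 ± 0.065, had adjusted p = 0.00814, and adjusted p = 0.316 with an estimated correlation. That call ended without replicate 3 of vehicle with TGF-beta1 (0.0672) and under quantile normalization (0.193, range 0.00109 to 0.193). Of 28 unfolded protein response genes, 1 was higher and 14 lower (2 and 17 adjusted over the list alone), with HSPA5 at -0.57 ± 0.043 (adjusted p = 0.000142). Of 35 ATF4 genes, 3 were higher and 25 lower (3 and 25 adjusted over the list alone), with STC2 at -0.88 ± 0.056 (adjusted p = 1.15e-05). Interferon-stimulated genes fell, and 1 was higher and 19 lower (1 and 21 adjusted over the list alone) of 26, with IFI35 at -1.32 ± 0.081 (adjusted p = 3.17e-06). Inflammatory cytokines and NF-kappaB target genes fell, with LIF at -1.15 ± 0.081 (adjusted p = 0.00228, and 0.369 with a filter at 5 FPKM, range 0.000995 to 0.369). Of 6 cholangiocyte and epithelial markers, 0 were higher and 4 lower (0 and 4 adjusted over the list alone), with KRT7 at -1.85 ± 0.15 and MUC1 at -1.44 ± 0.094. The camera test gave adjusted p = 0.00038, and adjusted p = 0.0796 with an estimated correlation. Of 6 portal fibroblast and mesothelial markers, 0 were higher and 4 lower (0 and 5 adjusted over the list alone), with ELN at -1.22 ± 0.11 and THY1 at -0.59 ± 0.056. This list had adjusted p = 0.00215, and adjusted p = 0.201 with an estimated correlation. All 10 histone genes tested were higher (median 1.54, adjusted p = 1.8e-11), with HIST1H2BK at 1.51 ± 0.047. Of the NRF2 targets, 16 were higher and 2 lower (17 and 2 adjusted over the list alone) of 25, with PGD at 0.57 ± 0.042 (adjusted p = 4.85e-07). Among the 5 tested aryl hydrocarbon receptor targets, 4 were higher and 0 lower (4 and 0 adjusted over the list alone). The cytochrome CYP1B1 was at 1.07 ± 0.070, and the list passed (camera, adjusted p = 0.00336). NQO1 and SLC7A5, named because they are shared, are also in the NRF2 and ATF4 lists, and CYP1A1 was below the filter. p53 target genes were ranked upwards, with DDB2 at 0.65 ± 0.072 (adjusted p = 0.028; adjusted p = 0.0627 with an estimated correlation). Cytosolic ribosomal protein genes were ranked downwards (median -0.14, RPS7 -0.41 ± 0.044, adjusted p = 2.41e-05; adjusted p = 0.272 with an estimated correlation), a direction that turned under quantile normalization (adjusted p = 0.95, range 1.13e-07 to 0.95). The median and mean of the cholesterol list were -0.002 and -0.007 while camera ranked it upwards (adjusted p = 0.762). The histone, NRF2, aryl hydrocarbon receptor, contractile, matrix, YAP, interferon, inflammatory, unfolded protein response and ATF4 calls held with an estimated correlation, with adjusted p at most 0.0333.

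**Figure D2:**
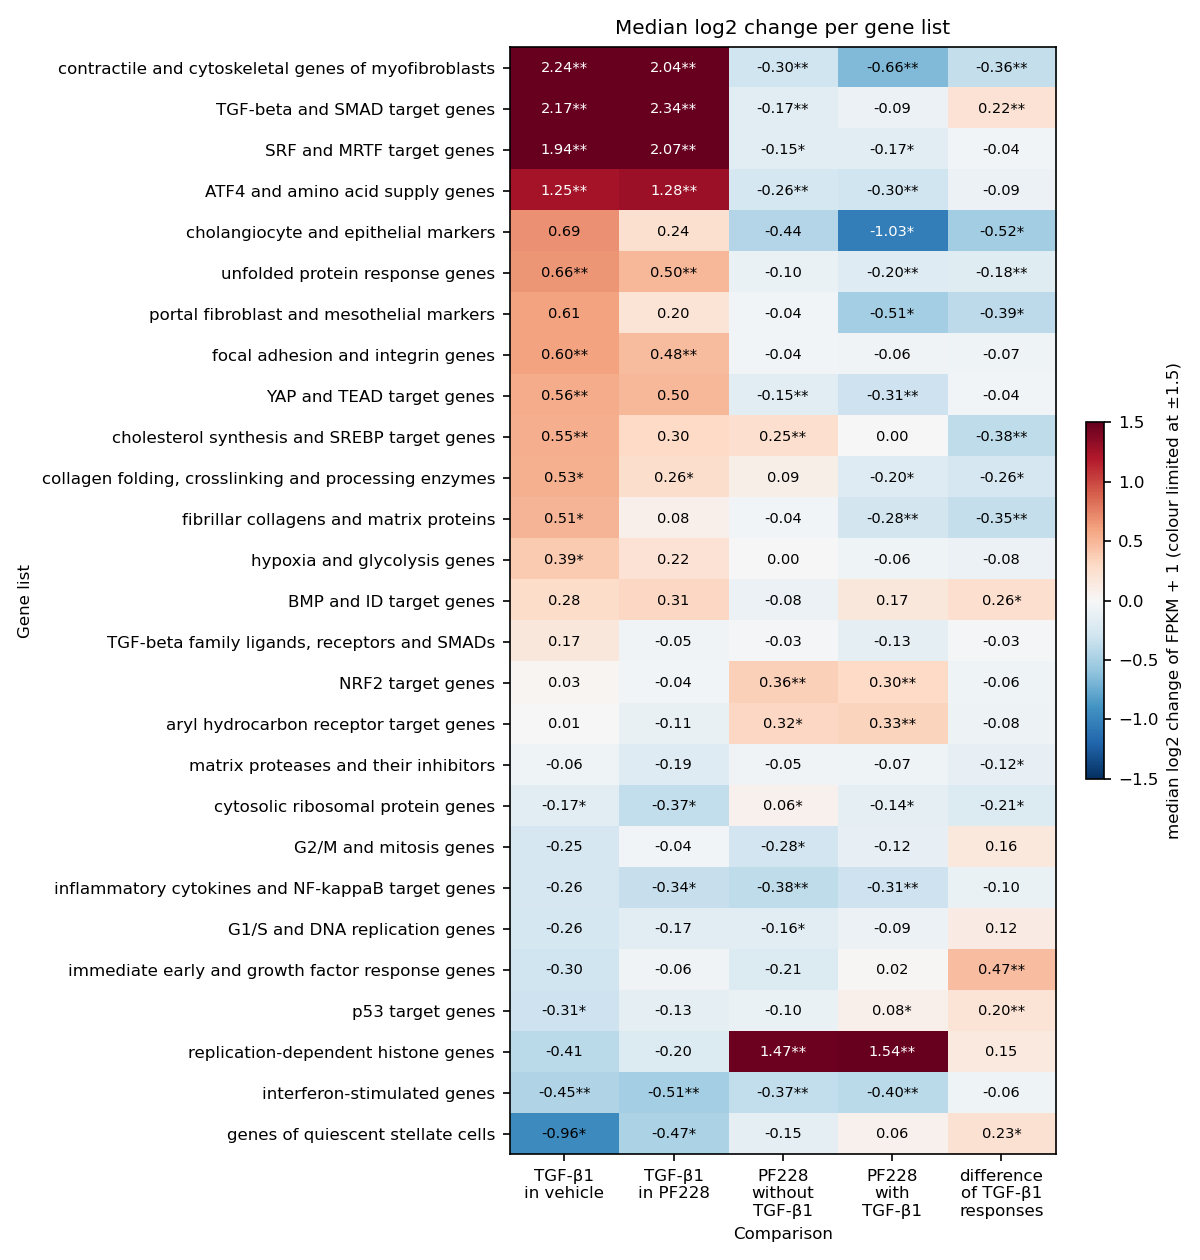
Median log2 change of FPKM + 1 over the tested members of 27 gene lists, in the 4 comparisons and in the difference between the TGF-beta1 responses with and without PF228, with colour limited at 1.5 in size, where 1 asterisk marks a camera call and a pair of asterisks a call that also held with an estimated correlation. The contractile list had medians of 2.24 with TGF-beta1 in vehicle and 2.04 in PF228.

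The interaction asked which TGF-beta1 responses differed between PF228 and vehicle. FN1 rose with TGF-beta1 in vehicle only, as a tested difference of -0.87 ± 0.050 (adjusted p = 6.48e-07) between a log2 change of 0.77 ± 0.036 in vehicle and one of -0.10 ± 0.036 in PF228. IGFBP3 (-2.14 ± 0.058), COMP (-2.47 ± 0.17), KRT7 (-1.97 ± 0.21), NINJ2 (-1.81 ± 0.32), the growth factor GDF6 (-1.74 ± 0.11) and the uncertain KRT18 (-2.54 ± 0.15) had the largest downward differences. KRT18 was at 3.16 ± 0.124 FPKM in PF228 and 3.44 ± 0.603 in PF228 with TGF-beta1 (SD, n = 3). GDF6, which is near 0 without TGF-beta1, was not called with a pseudocount of 0.01 (adjusted p = 0.165, range 1.87e-08 to 0.165). On the log2 scale ACTA2 kept most of its response, with a difference of -0.94 ± 0.079 (adjusted p = 9.32e-06). In FPKM it was clearly reduced, at 3982 to 4702 in vehicle with TGF-beta1 and 1998 to 2134 in PF228 with TGF-beta1. At the other end, the cadherin CDH6 went from 6.82 ± 0.167 to 11.7 ± 0.608 FPKM with TGF-beta1 in vehicle and from 3.21 ± 0.124 to 21.2 ± 0.8 in PF228 (1.70 ± 0.080), and CTGF gained 1.31 ± 0.047. SLC38A4 (1.64 ± 0.12) and TGM2 (1.50 ± 0.10) rose more in PF228, while RGCC (1.80 ± 0.20), ACKR4 (1.60 ± 0.15) and EGR3 (1.46 ± 0.10) fell less there, from lower starting levels. EGR3, for example, was at 2.94 ± 0.3 FPKM in vehicle and 0.0929 ± 0.0289 in PF228.

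In all, 1675 genes had a response that differed, 899 upwards and 776 downwards, of which 36 and 44 differed at least 2-fold. Of the 812 genes raised at least 2-fold in vehicle, 792 were also called higher in PF228, 20 were not called and 0 were called lower, and 253 (31.2%) had a significantly smaller and 71 a significantly larger response. Of the 702 genes lowered at least 2-fold, 690 were also lower, 11 were not called and 1 was higher in PF228, and the response of 267 (38.0%) was smaller and of 27 larger. In 20 simulations without an interaction on the same libraries, limma made 0 interaction calls. Residuals were drawn there for each gene on its own and pooled over the groups. The simulations thus left out any spread that genes of a library share and the larger spread of vehicle with TGF-beta1. They cannot tell whether such a spread gives interaction calls. The median share of the log2 response kept in PF228 was 0.845 (SD 0.003 over the 3 libraries of PF228 with TGF-beta1) across the 1514 genes. It was 0.877 for the raised and 0.803 for the lowered genes, and 0.861 when genes were chosen on other libraries than those measured.

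**Figure D3:**
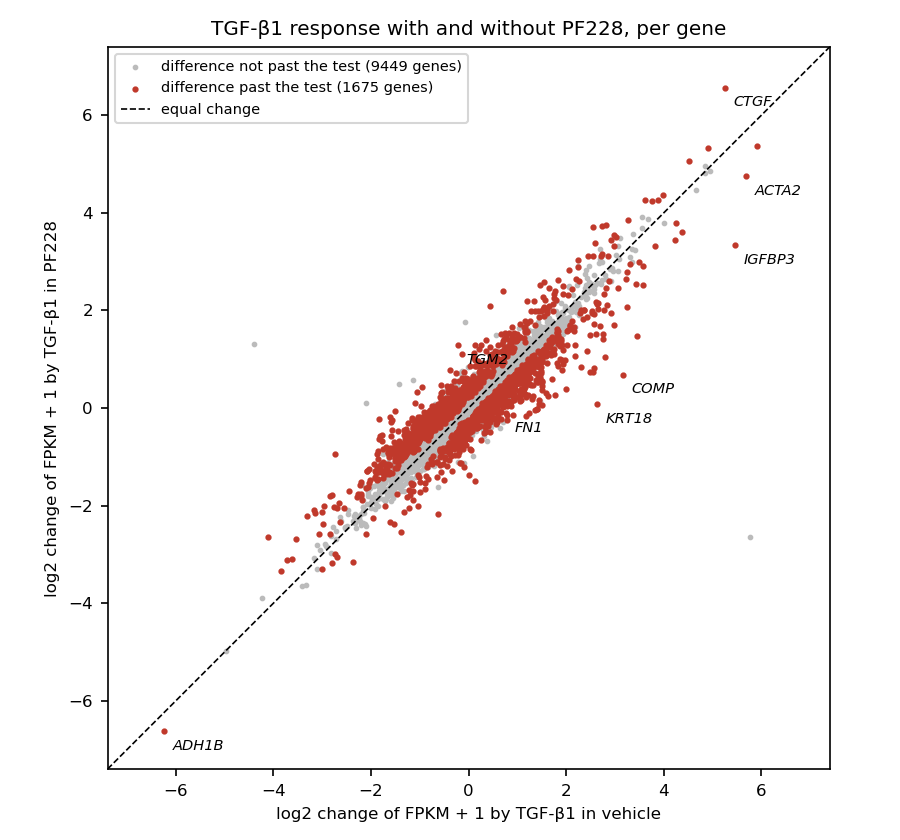
Log2 change of FPKM + 1 with TGF-beta1 in vehicle (horizontal axis) against that in PF228 (vertical axis), with 1 point per tested gene. The 1675 genes whose difference passed the test are in red, the others in grey, and the dashed line marks equal change (the outlying grey point at the lower right, SNHG25, is listed at 0 in some groups, and IGFBP3 lies below the line at 5.47 and 3.33).

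Gene lists were then tested for a shift of the TGF-beta1 response in PF228. Of 45 fibrillar collagens and matrix proteins, the TGF-beta1 response of 4 shifted up and of 23 down in PF228 (5 and 28 adjusted over the list alone; camera, adjusted p = 2.76e-12). They included TNC at -1.01 ± 0.073, COL5A2 at -0.47 ± 0.046, CCDC80 at -0.50 ± 0.050 and COL3A1 at -0.38 ± 0.054. The COL3A1 call ended under quantile normalization (adjusted p = 0.397, range 2.65e-06 to 0.397). COL3A1 was higher with PF228 alone and was not called with PF228 in the presence of TGF-beta1, so its smaller response came with a higher starting level. COL1A1 (-0.23 ± 0.12, adjusted p = 0.247) and COL1A2 (-0.17 ± 0.064, adjusted p = 0.1; 0.0222 without replicate 1 of vehicle with TGF-beta1, range 0.00212 to 0.289) did not pass, and both were called lower with library weights (0.0159 and 0.00212, range 0.00102 to 0.949 for COL1A1). Of 21 contractile genes, the response of 2 shifted up and of 11 down (3 and 12 adjusted over the list alone; adjusted p = 0.000406). They included DES at -1.27 ± 0.13, MYLK at -0.88 ± 0.088, TAGLN at -0.51 ± 0.088 and, upwards, TPM1 at 0.39 ± 0.054. Of 32 cholesterol synthesis genes, the response of 1 shifted up and of 18 down (1 and 23 adjusted over the list alone; adjusted p = 5.34e-11). They included MSMO1 at -0.74 ± 0.11, FADS1 at -0.44 ± 0.056 and SCD at -0.36 ± 0.049 (adjusted p = 0.742 under quantile normalization, range 1.94e-06 to 0.742). PF228 raised this list without TGF-beta1 (median 0.25, 19 higher and 3 lower). With TGF-beta1 present its median was -0.002, with 7 higher and 9 lower. The smaller response of the list thus came with a higher starting level, not with a lower level under TGF-beta1. Of 31 TGF-beta and SMAD target genes, by contrast, the response of 14 shifted up and of 3 down (15 and 4 adjusted over the list alone; adjusted p = 0.000295). They included HMGA2 at 0.87 ± 0.078 and SMAD7 at 0.40 ± 0.11. The SMAD7 call (adjusted p = 0.0286) ended without any of 6 libraries, replicate 1 of vehicle, replicate 2 of vehicle with TGF-beta1, and replicates 1 and 2 of PF228 and of PF228 with TGF-beta1 (adjusted p = 0.0506 to 0.0738), and under quantile normalization (0.0526, range 0.00551 to 0.0738). TGFBR2 fell less in PF228 (0.36 ± 0.058).

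Of 29 immediate early and growth factor response genes, the response of 16 shifted up and of 4 down (19 and 4 adjusted over the list alone; camera, adjusted p = 6.28e-06). They included ETV1 at 0.79 ± 0.097, SPRY2 at 0.68 ± 0.076 and, downwards, HBEGF at -1.27 ± 0.094. The p53 targets shifted up (median 0.20, adjusted p = 0.00113), with DDB2 at 0.62 ± 0.10, CCNG1 at 0.55 ± 0.11, PLK3 at 0.52 ± 0.11 and FAS at 0.50 ± 0.078. Unfolded protein response genes shifted down (median -0.18, adjusted p = 0.00117, and 0.0661 under quantile normalization, range 0.000167 to 0.0661), with SEL1L3 at -0.57 ± 0.091, SEC24D at -0.29 ± 0.060, PDIA6 at -0.23 ± 0.057 and CALR at -0.20 ± 0.048. The calls of PDIA6 and CALR ended under quantile normalization (adjusted p = 0.0511 and 0.718, range 0.000227 to 0.0511 and range 0.000891 to 0.718), and that of CALR also without the intensity trend (0.0541). These and the matrix, contractile, cholesterol and SMAD calls held with an estimated correlation (adjusted p at most 0.0366). Other camera calls were lost with it. The cholangiocyte and epithelial markers, with KRT18 and KRT7, shifted down (adjusted p = 0.00117; adjusted p = 0.114 with an estimated correlation), as did the portal fibroblast and mesothelial markers (adjusted p = 0.00142; adjusted p = 0.21 with an estimated correlation, and 0.0576 without the filter, range 0.000234 to 0.0576). The same direction held for the collagen folding, crosslinking and processing enzymes (adjusted p = 0.000714; adjusted p = 0.215 with an estimated correlation) and the matrix proteases and their inhibitors (adjusted p = 0.0128; adjusted p = 0.0961 with an estimated correlation, and 0.494 under quantile normalization, range 0.00679 to 0.494). The genes of quiescent stellate cells shifted up (adjusted p = 0.0128; adjusted p = 0.0605 with an estimated correlation, and 0.273 with a filter at 5 FPKM, range 0.0085 to 0.273). So did BMP and ID target genes (adjusted p = 0.0128; adjusted p = 0.131 with an estimated correlation, 0.0539 without replicate 2 of PF228 with TGF-beta1 and 0.0661 under quantile normalization, range 0.00574 to 0.0661). The cytosolic ribosomal protein genes shifted down (adjusted p = 3.62e-11; adjusted p = 0.131 with an estimated correlation), a direction that turned under quantile normalization (adjusted p = 0.896, range 1.98e-15 to 0.896). The list of focal adhesion and integrin genes did not pass (adjusted p = 0.0557), except without replicate 1 of vehicle with TGF-beta1 (0.0371) or replicate 2 of PF228 (0.0393) and under 6 other alternatives (range 0.0178 to 0.473). The aryl hydrocarbon receptor and NRF2 lists had medians of -0.08 and -0.06, means of 0.02 and 0.02, and did not pass (adjusted p = 0.692 and 0.456).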

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

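The tests that weigh an explanation in this part were chosen after the results were seen, as were the splits with an effect removed, and the other splits of the samples before. The results below were singled out because the TGF-beta1 response differed between PF228 and vehicle by a test of the difference itself. They were 1675 genes in all. Groups of 3 libraries were not tested for outlying samples. Among the largest differences (TGF-beta1 response in PF228 minus that in vehicle, log2 ± SE), the upward ones were RGCC 1.80 ± 0.20, CDH6 1.70 ± 0.080, SLC38A4 1.64 ± 0.12, ACKR4 1.60 ± 0.15, TGM2 1.50 ± 0.10 and EGR3 1.46 ± 0.10. The downward ones were KRT18 -2.54 ± 0.15, COMP -2.47 ± 0.17, IGFBP3 -2.14 ± 0.058, KRT7 -1.97 ± 0.21, NINJ2 -1.81 ± 0.32 and GDF6 -1.74 ± 0.11. Of the genes named in advance, ACTA2 differed by -0.94 ± 0.079, TAGLN by -0.51 ± 0.088, FN1 by -0.87 ± 0.050, COL3A1 by -0.38 ± 0.054, TGFBR2 by 0.36 ± 0.058, SMAD7 by 0.40 ± 0.11 and CTGF by 1.31 ± 0.047.

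By gene list, the SMAD target HMGA2 differed by 0.87 ± 0.078. The contractile genes MYLK, DES and TPM1 differed by -0.88 ± 0.088, -1.27 ± 0.13 and 0.39 ± 0.054. The matrix genes TNC, COL5A2 and CCDC80 differed by -1.01 ± 0.073, -0.47 ± 0.046 and -0.50 ± 0.050. The SREBP targets MSMO1, FADS1 and SCD differed by -0.74 ± 0.11, -0.44 ± 0.056 and -0.36 ± 0.049. The immediate early and growth factor response genes HBEGF, SPRY2 and ETV1 differed by -1.27 ± 0.094, 0.68 ± 0.076 and 0.79 ± 0.097. The p53 targets FAS, DDB2, CCNG1 and PLK3 differed by 0.50 ± 0.078, 0.62 ± 0.10, 0.55 ± 0.11 and 0.52 ± 0.11. The unfolded protein response genes SEL1L3, SEC24D, PDIA6 and CALR differed by -0.57 ± 0.091, -0.29 ± 0.060, -0.23 ± 0.057 and -0.20 ± 0.048. In 3 of 100 splits that moved the PF228 label within each TGF-beta1 state, the real one included, as many genes as the real 1675 were called. These splits do not decide on chance, because they keep the PF228 effect that both states share. The highest of the others called 5335 genes and exchanged the label in the TGF-beta1 libraries alone, which adds the effects of PF228 and points to that structure of the samples. With the shared PF228 effect removed, 1 of the same 100 splits, the real one, called as many as the real 1675 and the highest other called 1. The removal used the real labels, which by itself keeps the real count and brings the split that had called 5335 genes near 0. These splits therefore do not decide on chance either.

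In the TGF-beta and SMAD target list, 14 members had a larger log2 response to TGF-beta1 in PF228. Of these, 10 were lower with PF228 alone, 6 were higher with PF228 and TGF-beta1 and 2 were both, so a lower starting level may account for much of the pattern, in a test that could have come out the other way. A pseudocount that shrinks low values was argued against by the 13 of 14 that kept their call with a pseudocount of 0.01, and GC bias of the libraries as the whole cause by the 14 of 14 that kept it with each library's GC trend removed. The 4 members not lower with PF228 alone were SMAD7, PMEPA1, TGIF1 and TSC22D1, which are named because they are the exceptions. The 2 that were both were NEDD9 and SMURF2 (each 0.31 with PF228 in the presence of TGF-beta1), named for that reason. A lower starting level does not account for their higher level with PF228 and TGF-beta1. For these 2 and the 4 exceptions an effect of the inhibitor on the response itself stays open. So does a spread between samples that is technical, since the labels do not give separate cultures.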

How the results depend on the processing

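Library weights, the scalings and the other alternatives were planned, except that the first residual component as a covariate and the removal of the GC trend were chosen after seeing the data. Counts of changed genes stayed within 1.5 times under every alternative but the following, and the cause was not tested except where the construction gives it. With a 2-fold minimum, which removes small changes by construction, 1514 genes changed with TGF-beta1 in vehicle, 1134 with TGF-beta1 in PF228, 115 with PF228 without TGF-beta1, 162 with PF228 with TGF-beta1 and 80 in the interaction. Library weights, whose estimate did not fully converge, gave 6763 genes for PF228 with TGF-beta1 and 4053 for the interaction. The residual component gave 3310 interaction genes and the GC trend removed 2806. With 1 library left out, PF228 without TGF-beta1 had 2893 to 4520 calls and the interaction 1203 to 2063. The share of higher genes moved by over 10 points for TGF-beta1 in PF228 with upper-quartile scaling (41.0% against 51.6%) and for PF228 without TGF-beta1 with quantile normalization (51.4% against 40.7%). Upper-quartile scaling shifted the median of all genes by -0.098 with TGF-beta1 in vehicle and by -0.100 with TGF-beta1 in PF228, so small changes with TGF-beta1 hold only relative to that choice. Gene lists past the test with an estimated correlation numbered 9 for TGF-beta1 in vehicle, 7 for TGF-beta1 in PF228, 9 for PF228 without TGF-beta1, 10 for PF228 with TGF-beta1 and 7 for the interaction. With fry, which asks whether a list moves 1 way and not whether it differs from other genes, they numbered 27, 26, 23 and 25 in the first 4 of these.

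The median share of the TGF-beta1 response kept in PF228 was 0.845, with an SD of 0.003 over the 3 libraries of PF228 with TGF-beta1. That SD leaves out the spread of the other libraries. The share moved by more than this SD to 0.852 and 0.856 with pseudocounts of 0.1 and 0.01, 0.841 without a filter, 0.866 with a filter at 5 FPKM, 0.833 with library weights, 0.851 with the GC trend removed, 0.808 with a log2 minimum of 0.5 and 0.861 with genes chosen on other libraries. With 1 library left out it ranged from 0.832 to 0.846. Over 600 pairs of a named gene and a comparison and 14807 alternatives of these, 14507 kept their side of the threshold. Another 172 lost the call, 124 gained one and 4 changed sign with the main or the alternative value past the test, in 85 pairs. Changes of sign between values that both did not pass were counted among the 14507. The 4 changes of sign that involved a call came with quantile normalization, in none of them were both values past the test, and their cause was not tested. They were NQO1 with TGF-beta1 in vehicle (-0.073), COL1A2 (-0.155) and COL3A1 (0.207) with PF228 with TGF-beta1, and RPL6 in the interaction (0.009). The fit of only the compared groups gave no value for the interaction, which needs all groups. The replicate numbers did not pair the samples. Of 18 pairs of libraries with the same number, correlations of deviations ran from -0.39 to 0.38 with 4 over 0.1, and 4 of 12 libraries correlated best with their own number. With the replicate block, 7649, 7200, 3545, 3686 and 1394 genes were called in the order above. Depth in reads is unknown, so values near 0 have no interval.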

Other observations

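Except for the splits of the samples, the tests of explanations in this part were chosen after the results were seen. Single immediate early and growth factor response genes differed with PF228, although their list did not pass in either state. Without TGF-beta1, the flow-responsive factor KLF2 (log2 change 1.51 ± 0.12, adjusted p = 1.6e-06) and KLF4 (0.67 ± 0.045) rose and the phosphatase DUSP5 fell (-0.88 ± 0.083). Of 29 immediate early and growth factor response genes, 6 were higher and 15 lower (7 and 15 adjusted over the list alone; camera, adjusted p = 0.0786), and the list passed only without replicate 3 of vehicle (0.0456) and without the filter (0.00825, range 0.00825 to 0.952). With TGF-beta1, KLF4 (1.03 ± 0.045) and SPRY2 (1.01 ± 0.054) were higher with PF228, and HBEGF (-1.33 ± 0.066) and EGR2 (-0.84 ± 0.067) lower. Of the list, 12 were higher and 6 lower (12 and 6 adjusted over the list alone) in that state (camera, adjusted p = 0.0976).

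Ligands, receptors and regulators of the TGF-beta family went both ways with PF228, and their list did not pass in either state. Without TGF-beta1, 3 were higher and 11 lower (3 and 11 adjusted over the list alone) of 35 (camera, adjusted p = 0.166). BMP6 (-0.85 ± 0.060), the receptor ACVRL1 (-0.96 ± 0.070) and LTBP1, which stores latent TGF-beta in the matrix (-0.51 ± 0.037), were lower and TGFBR2 higher (0.16 ± 0.041). With TGF-beta1, TGFB2 (-1.29 ± 0.073), INHBA (-1.16 ± 0.089) and GDF6 (-1.76 ± 0.075) were lower and TGFBR2 higher (0.52 ± 0.041). Of 35 TGF-beta family ligands, receptors and SMADs with TGF-beta1 present, 7 were higher and 13 lower (7 and 13 adjusted over the list alone; camera, adjusted p = 0.0569), and the list passed without replicate 1 of vehicle with TGF-beta1 (0.0479), replicate 2 of PF228 with TGF-beta1 (0.0412) or the filter (range 0.014 to 0.369). Of the genes of quiescent stellate cells, IGFBP5 was higher with PF228 in both states (0.28 ± 0.036 and 0.58 ± 0.036). The lists of genes of quiescent stellate cells and of hypoxia and glycolysis genes did not pass with PF228 alone (adjusted p = 0.234 and 0.604).

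PF228 without TGF-beta1 gave many calls of small size, 3883 genes of which 115 changed at least 2-fold. The first component of the residuals within groups held 36.3% of their variance and correlated with GC content across 10320 genes (Spearman's rho -0.821), but it was carried mainly by replicates 1 and 3 of vehicle with TGF-beta1, which are not compared here. The log2 changes of this comparison correlated with GC content (rho 0.274, across genes, which are not independent replicates), as did the interaction (-0.215). With each library's GC trend removed, 4760 genes were called against 3718 of the same genes without the removal. The higher total does not decide on GC bias, since the removal also takes out spread within groups. Of the 3883 calls, 3511 were kept with the removal, which argues against GC bias of the libraries as the whole cause. A technical spread between samples stays open, since the labels do not give separate cultures, and so does an effect of PF228 as the biological explanation.

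The 10 tested replication-dependent histone genes were higher with PF228 in both states, although their mRNAs normally lack the poly(A) tail that the libraries select. The filter counted the PF228 libraries too, so genes high only there could pass it. Those of the 18 histone genes in the table that were below it stayed at or below 0.891 FPKM in every library. That is too low to tell whether they changed. GC bias of the libraries was argued against as the whole cause, since the lower of the 2 medians with the GC trend removed was 1.46 and all 10 kept their call in both states. More cells in S phase was argued against only without TGF-beta1, where the G1/S and DNA replication genes had a median of -0.157 with 1 higher and 9 lower of 22 (camera, adjusted p = 0.0309; adjusted p = 0.0719 with an estimated correlation and 0.239 with a filter at 5 FPKM, range 0.0164 to 0.239), and stays open with TGF-beta1, where the list did not pass (median -0.091, 2 higher and 5 lower, adjusted p = 0.471). Weaker poly(A) selection stays open, because 6 tested RNAs without a tail had SEs of up to 0.83 around medians of 0.61 without and 0.28 with TGF-beta1, against histone medians of 1.47 and 1.54. They ran from -0.33 (RMRP) to 1.67 (RN7SL1), and RN7SK was at -0.02 without and 0.41 with TGF-beta1. RN7SK was the most abundant of the 6 except in PF228 with TGF-beta1, where it was at 15.49 FPKM and RN7SL1 at 38.52. Tailed histone transcripts in the presence of PF228 are then a possible explanation that was not tested.

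For the 4 comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05. Every split but the real one also mixes the compared groups. That puts the effect of the treatment into the residuals and by itself keeps the calls of the other splits low. These splits therefore do not decide on chance. In each of them 1 of the 10 splits, the real one, called as many genes as the real grouping. TGF-beta1 changed 7805 genes in vehicle, where the highest other split called 0, and 7357 in PF228, where it called 2. PF228 changed 3883 genes without and 3995 with TGF-beta1, where the highest other split called 0.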
